A study of Mus musculus with 10 samples.

How the data were processed

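Gene expression was measured by RNA sequencing of total RNA from trigeminal ganglia of mouse embryos (strain C57Bl6) at embryonic day 13.5. Per the labels' protocols, the tissue was microdissected in cold buffer and stored in TRIZOL, RNA was extracted with an RNAspin column kit, and libraries followed standard Illumina protocols. The labels name no cell sorting, so each library was taken to hold the dissected ganglion with whatever glia, vessels and neighbouring tissue came with it. The genotype label put 5 samples in the Prdm12-/- group (knockout replicates 16, 29, 42, 49 and 50) and 5 in the Prdm12+/+ group (wild-type replicates 22, 24, 32, 35 and 45), and all 10 carry the label Sox10 Venus+. Replicate numbers come from the sample titles. No number occurs in both groups, so samples were not paired. The labels do not say that each library came from a different embryo, so p-values measure the spread between these samples, which may in part be technical. The titles also start with a different letter in each group, so any handling difference that the letter marks cannot be separated from genotype.

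The deposited files hold raw counts per gene, 1 file per sample, with 55414 Ensembl gene IDs in the same order in every file. The authors used bcl2fastq 2.20.0.422, STAR 2.7.10a and featureCounts 1.5.0-p1, per the submitters' processing notes, which also name the builds GRCm39 and mm10 without saying what each was used for. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads shared between near-identical genes, and reads of overlapping or antisense genes, may therefore be assigned to either gene or to none. Gene symbols were taken from a table of ID and symbol pairs, which matched 52081 of the IDs. Because 2147 IDs belong to a newer ID series than the GRCm38 annotation at hand, no genome coordinates are given, and a RefSeq gene table was used only for which genes neighbour each other. The labels do not say which part of Prdm12 the mutant allele lacks, so the gene-level count of Prdm12 need not fall to 0.

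Total counts per library ranged from 3258010 (knockout 49) to 33556000 (knockout 16), with 13603700 in knockout 29. A floor of 3 counts corresponds to 0.869 CPM (counts scaled to a fixed library total, with TMM factors) in knockout 49, 0.236 CPM in knockout 29 and 0.0889 to 0.107 CPM in the others. Counting intervals cover counting error only. Libraries of the same group were compared for duplicates with a chi-square statistic over genes with at least 200 counts in all libraries together. It was at least 10.0 per gene in all 20 pairs, so no library repeated the counts of another and all were kept. The lowest value was between wild-type 32 and 35, which also had the highest rank correlation of all pairs (0.996). Whether they came from different embryos cannot be told from this check.

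Genes were kept with filterByExpr of edgeR (minimum count 10), which left 18005. Counts were scaled with TMM factors, and the genotypes were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05 on the adjusted p. CPM values are TMM-scaled and given as mean ± SD with n = 5 per group, and log2 fold changes are knockout over wild type with their standard error (SE). All adjusted p-values of genes come from this edgeR test unless another test is named. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Before the data were examined, 26 gene lists were fixed: nociceptors, mechanoreceptors and proprioceptors, visceral sensory neurons, autonomic and noradrenergic neurons, sensory transcription factors, general neuronal genes, neurogenesis, neurotrophic factors and receptors, neuropeptides, glia, melanocytes, mesenchyme, cartilage and bone, endothelium, erythroid cells, muscle, epithelium, macrophages, central nervous system, Hox genes, apoptosis and p53 targets, proliferation, immediate early genes, mitochondrial transcripts, the other Prdm genes and sex-linked genes. The lists overlap: 9 of 17 nociceptor, 8 of 17 neuropeptide and 6 of 18 neurotrophic members are also in another list. A gene such as Gal, Ret or Ntrk2 is therefore counted in more than 1 list. Each list was tested with camera (preset correlation 0.01) with adjustment over the 26 lists, again with an estimated correlation, and with fry. Counts adjusted over a list alone apply the same adjustment within that list. A list's score in a library is the mean log2 CPM of its members (prior count 2).

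Single values were compared with exact two-sided permutation tests over the 252 assignments of 5 libraries among 10, for which the smallest possible p is 0.00794. The named genes follow a rule fixed before the data were examined. They include Prdm12 and Phox2a, and the 10 genes with the largest change in each direction among those past the threshold with a mean of at least 1 CPM and no overlap between the groups, leaving out Prdm12, sex-linked genes and genes without a symbol or with a predicted-gene symbol. They also include the 4 members of smallest p among the called members of each list, or in a list with fewer than 2 called members its 2 most abundant members, and all sex-linked genes of the list. Genes named outside the rule are said to be. Some genes that the rule takes are not reported here.

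The test was first tried on simulated counts with the means, dispersions and library sizes of these libraries. For the comparison of knockout with wild type, over 17673 simulated genes, it recovered 33% of 100 genes changed 2-fold and 72% of 100 genes changed 4-fold. Of the genes called there, 7.89% had not been changed. Each gene was drawn independently of the others. The simulation therefore lacked differences between libraries that many genes share, and its rates may not hold for the real comparison. The alternatives tried were other scalings, other filters on low counts, DESeq2, limma-voom, robust fitting, 1 surrogate variable and leaving out each library in turn. After the data were seen, fits without knockout 29 and 49 together were added. Fits with the mesenchyme score, the central nervous system score or Xist as a covariate were added then too. So were permutation tests of single genes other than Prdm12, whose test was planned.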

Results

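RNA was sequenced from trigeminal ganglia, the cranial ganglia that hold the touch, pain and temperature neurons of the face, of mouse embryos with or without Prdm12. Prdm12 encodes a zinc finger protein of the PRDM family that is needed for the development of nociceptors. Each genotype was represented by 5 libraries. Total counts per library ranged from 3258010 in knockout 49 and 13603700 in knockout 29 to 33556000 in knockout 16. The totals of the other 7 libraries lay between 27308300 (knockout 42) and 32045800 (wild-type 24). The comparison asks what the absence of Prdm12 changed in the ganglion's transcriptome.

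Prdm12 itself (ENSMUSG00000079466) was lower in every knockout library than in every wild-type library. It stood at 18.2 ± 14.1 CPM in the knockout and 182 ± 76.7 CPM in the wild type (SD, n = 5 each), a log2 fold change of -3.32 (SE 0.49, adjusted p = 0.0156). An exact two-sided permutation test gave p = 0.00794, the smallest that 5 against 5 libraries allow. The remaining counts were 8.74, 42.7, 10.1, 12.2 and 17.0 CPM in knockout libraries 16, 29, 42, 49 and 50, against 74.3 to 264 CPM in the wild type. Among the other Prdm genes, 0 of 12 tested members passed the threshold, none did when adjusted over the list alone, and the set was not called (camera adjusted p = 0.844). Prdm2 was at 106 ± 4.37 CPM in the knockout and 102 ± 6.89 CPM in the wild type, and Prdm4 at 78.5 ± 8.12 and 85.7 ± 6.98 CPM.

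Nociceptor genes fell in the knockout. Scn10a (ENSMUSG00000034533), the sodium channel Nav1.8, fell from 307 ± 158 to 11.4 ± 8.50 CPM (log2 fold change -4.76, SE 0.56, adjusted p = 0.00336), and Trpv1, the capsaicin and heat receptor, from 30.5 ± 22.6 to 1.34 ± 0.357 CPM. Runx1, a transcription factor of the nociceptor lineage, fell from 90.1 ± 36.8 to 16.3 ± 1.43 CPM, and the neuropeptide galanin, encoded by Gal, from 97.6 ± 41.4 to 11.5 ± 4.63 CPM. Of 16 tested genes of the nociceptor list, 5 fell, these 4 among them, 0 rose and 11 did not pass. Adjusted over the list alone, 11 members were lower and 1, Trpa1, was higher. Trpa1 was at 3.22 CPM in the knockout and 1.09 CPM in the wild type, with overlap between the groups (adjusted p = 0.245 over all genes). Its highest values were 5.21 CPM in knockout 49 and 6.12 CPM in knockout 50. Members that did not pass over all genes included Scn9a (335 against 714 CPM in the wild type) and P2rx3 (324 against 443 CPM). Tlx3 was at 222 CPM in knockout 29 and at 27.2 to 41.7 CPM in the other knockout libraries, against 42.6 to 85.6 CPM in the wild type, and Calca ranged from 8.88 to 179 CPM in the knockout and from 11.4 to 80.4 CPM in the wild type. The list as a set was lower in the knockout (median log2 fold change -1.13, camera adjusted p = 1.52e-23), and this held with an estimated correlation (adjusted p = 0.0189). Its score was 3.83 ± 0.131 in the knockout and 5.55 ± 0.293 in the wild type. The highest nociceptor scores, 5.85 and 5.86, came from wild-type libraries 32 and 35, which also had the lowest mesenchyme scores of all libraries, 3.77 and 4.20.

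**Figure D1:**
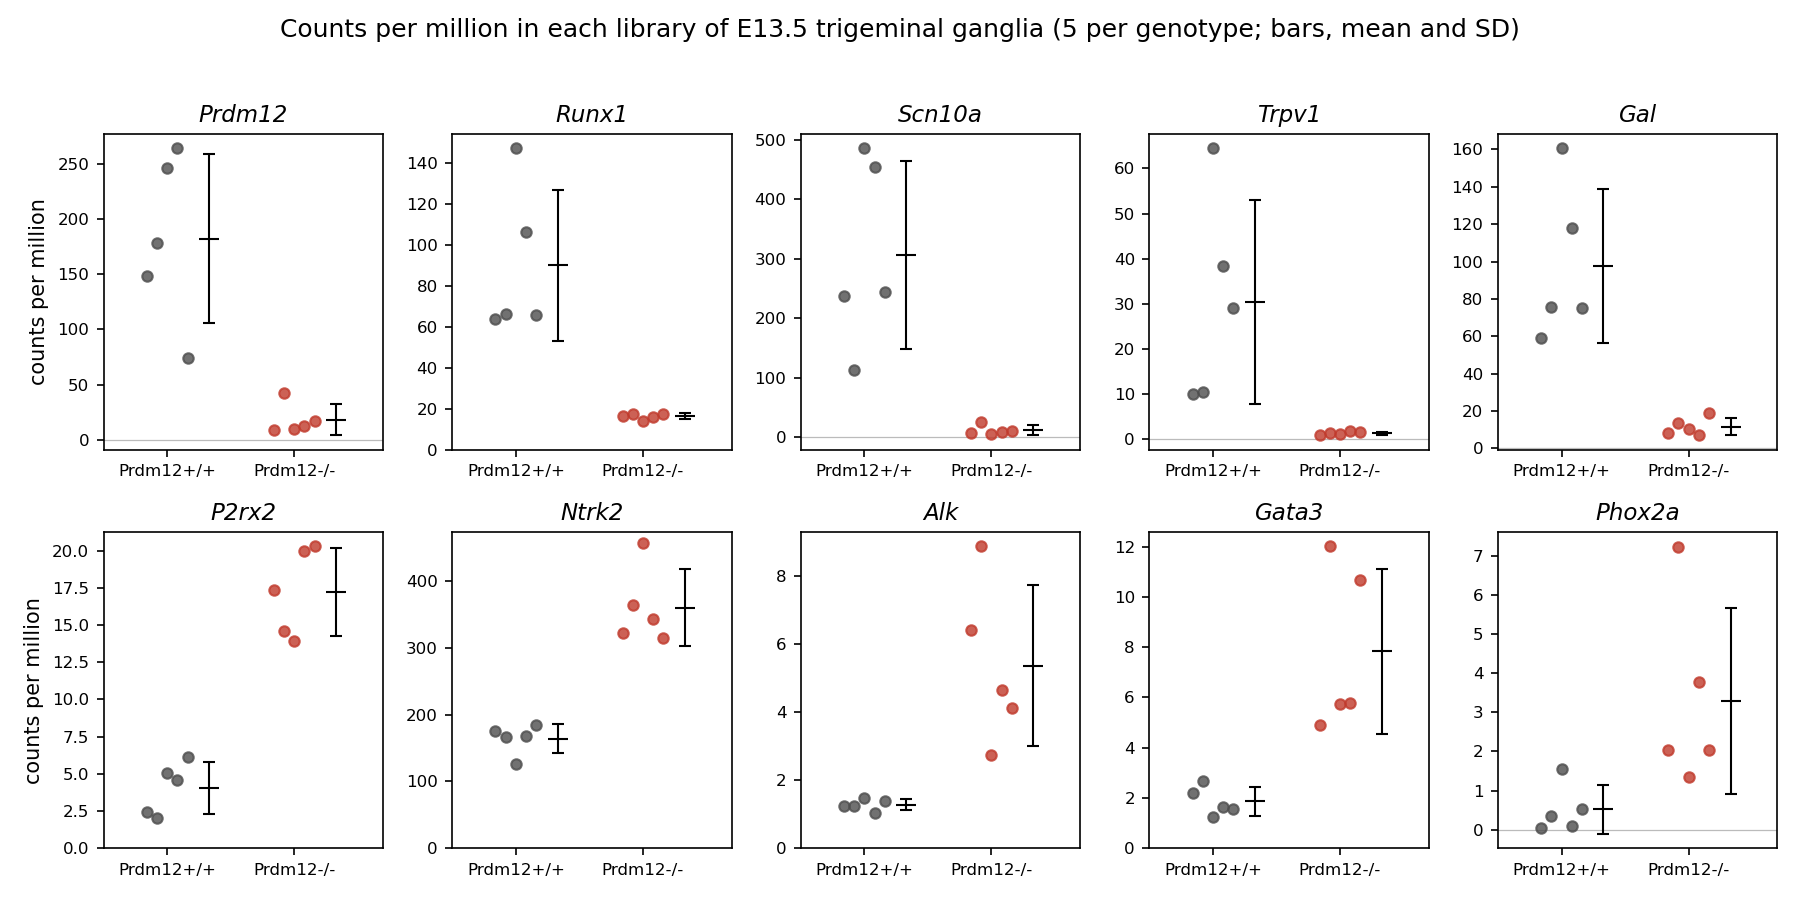
CPM (vertical axes, linear, a separate scale for each gene) of 10 genes in each of 5 Prdm12+/+ libraries (grey points) and 5 Prdm12-/- libraries (red points); bars give the mean and SD. The genotypes did not overlap for any gene shown except Phox2a, with Scn10a at 307 CPM in the wild type and 11.4 CPM in the knockout, and P2rx2 at 4.03 and 17.2 CPM. For Scn10a, Trpv1, P2rx2, Alk and Gata3, lack of overlap was part of the rule that named them.

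Genes for neurotrophic factors and their receptors moved in both directions. Ntrk2, the receptor for brain-derived neurotrophic factor, rose from 164 ± 22.3 to 360 ± 57.3 CPM (log2 fold change 1.14, SE 0.15, adjusted p = 0.00682), and Bdnf itself rose from 5.29 ± 0.580 to 10.7 ± 0.878 CPM. Ret, the signalling receptor for the GDNF family, fell from 222 ± 108 to 60.6 ± 14.4 CPM. Ntrk2 was called in all 23 alternative analyses, but Bdnf and Ret in 11 each (adjusted p up to 0.0977 and 0.154), always in the same direction. Of 18 tested genes for neurotrophic factors and receptors, 2 rose (Ntrk2 and Bdnf), 2 fell (Ret among them) and 14 did not pass. Adjusted over the list alone, 5 were higher and 3 lower. The set test gave no call (camera adjusted p = 0.456, with a median of 0.19, a mean of -0.16 and an upward direction).

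Among 16 tested mechanoreceptor and proprioceptor genes, Ntrk2 rose, Mafa and Ret fell, and 13 did not pass. Mafa, a transcription factor of early Ret-expressing mechanoreceptors, fell 8.79-fold to 1.55 ± 1.07 CPM (log2 fold change -3.14, SE 0.53, adjusted p = 0.0287), and was called in 13 of 23 alternatives. Adjusted over the list alone, Ntrk3 and Runx3 joined Ntrk2 among 3 higher genes, and Calb1 joined Mafa and Ret among 3 lower ones. Ntrk3 and Runx3 mark some mechanoreceptors as well as proprioceptors, and whether these ganglia held proprioceptors was not tested. Runx3 was at 92.5 CPM in knockout 29 and 22.9 to 41.7 CPM in the other knockout libraries, against 10.4 to 18.4 CPM in the wild type. Ntrk3 stood at 348 ± 126 CPM in the knockout and 158 ± 51.4 CPM in the wild type, with an adjusted p of 0.166 over all genes. The set test gave no call (adjusted p = 0.997; median log2 fold change -0.03, test direction up).

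Genes of visceral sensory neurons showed a mixed picture. P2rx2, a subunit of ATP-gated channels, rose from 4.03 ± 1.74 to 17.2 ± 2.96 CPM (log2 fold change 2.09, SE 0.31, adjusted p = 0.0152) and was the 1 called gene of 12 tested. Phox2a, a homeobox gene of visceral neurons, was at 3.29 ± 2.38 and 0.515 ± 0.616 CPM with overlap between the groups (log2 fold change 2.64, SE 0.80, adjusted p = 0.209). An exact two-sided permutation test of log2(CPM + 1), 1 of 3 permutation tests of single genes chosen after the values were seen, gave p = 0.0159 for Phox2a (0.0159 adjusted over the 2 tests on this scale). Adjusted over the list alone, 4 visceral sensory genes were higher and 3 lower. Tbx3 stood at 104 ± 50.5 and 99.1 ± 25.8 CPM. The set test gave no call (adjusted p = 0.236). Markers of the central nervous system were high in single libraries of both genotypes: Pax2 was at 53.6 CPM in knockout 16, 13.4 CPM in wild-type 24 and 9.58 CPM in wild-type 45, and Lhx1 was also highest in these libraries, in the same order. The central nervous system score was 1.10 ± 1.87 in the knockout and -0.50 ± 2.23 in the wild type.

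Among autonomic and noradrenergic genes, Gata3, a transcription factor of sympathetic neurons among other cell types, rose from 1.86 ± 0.574 to 7.83 ± 3.28 CPM, while Th, which encodes the enzyme that limits catecholamine synthesis, fell from 146 ± 58.7 to 35.7 ± 12.1 CPM. Gata3 was called in 14 and Th in 17 of 23 alternatives. The other 14 of 16 tested members did not pass. Adjusted over the list alone, 6 were higher and 1 was lower. The set was called higher by camera (adjusted p = 0.00991), which was lost with an estimated correlation (adjusted p = 0.670 with an estimated correlation).

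Over all 18005 tested genes, 17 rose and 67 fell, and 2364 had an unadjusted p under 0.05. Of the 84 called genes, 83 had every knockout library on 1 side of every wild-type library, as did 4.21% of all tested genes, where chance gives 0.794%. A fold change of at least 2 was reached by 13 of the higher and 64 of the lower genes. The lower genes with the largest changes included 3 olfactory receptor genes, Olfr559, Olfr78 and Olfr558. Olfr558 went from 21.4 ± 7.90 to 0.957 ± 0.526 CPM, Olfr78 from 8.60 ± 4.93 to 0.196 ± 0.163 CPM, and Olfr559 was left with 3 counts in all knockout libraries together against 292 in the wild type, a ratio of rates of 68.8 (95% interval 23.3 to 336, counting error only). How reads shared between receptor genes were counted is not given in the sources used here. Cdkl4, a cyclin-dependent kinase-like gene, fell from 22.3 ± 6.54 to 1.23 ± 0.291 CPM, and Bhlhe23, a basic helix-loop-helix transcription factor, from 9.66 ± 3.65 to 0.605 ± 0.742 CPM, though the call for Bhlhe23 was made in 14 of 23 alternatives. Bhlhe23 was at 1.89 CPM in knockout 29 and at 0.107 to 0.594 CPM in the other knockout libraries. Ccdc68 fell from 5.36 ± 1.88 to 0.452 ± 0.168 CPM and the monooxygenase Fmo2 from 4.57 ± 1.10 to 0.454 ± 0.197 CPM.

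The higher genes with the largest changes were expressed at low to moderate levels. Tmc3, a transmembrane channel-like gene, rose from 0.409 ± 0.254 to 2.40 ± 0.560 CPM, and Slc7a11, the cystine and glutamate exchanger, from 5.58 ± 2.14 to 30.9 ± 19.3 CPM. Alk, a receptor tyrosine kinase of developing neurons, rose from 1.27 ± 0.164 to 5.36 ± 2.37 CPM, and C1ql3, a secreted synaptic protein gene, from 0.793 ± 0.295 to 2.72 ± 0.847 CPM. Slc6a11, a GABA transporter gene, rose from 3.80 ± 1.16 to 12.1 ± 5.13 CPM and Adora2a, an adenosine receptor gene, from 4.53 ± 0.726 to 11.2 ± 3.47 CPM. Cpne7 rose from 0.675 ± 0.212 to 2.02 ± 0.330 CPM, and Abcc3 rose 2.66-fold from 1.86 ± 0.570 CPM. Alk was called in 18 of 23 alternatives and the other 7 of these genes in 9 to 14. These counts were sensitive to single libraries, with 2 to 35 higher and 27 to 88 lower genes when each library was left out in turn, and the Prdm12 call was lost without knockout 49 (adjusted p = 0.0561) and without knockout 50 (adjusted p = 0.0616). DESeq2 called 388 genes higher and 236 lower, among them all 84, and of its 371 further higher genes 43.9% were separated between the genotypes in every library. Of its 169 further lower genes, 108 were separated in this way.

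General neuronal genes did not pass singly: 0 of 20 tested members were called, and 1, Elavl4, was lower when adjusted over the list alone. Nefm was at 2594 ± 1334 CPM in the knockout and 2824 ± 864 CPM in the wild type, and Tubb3 at 1821 ± 984 and 1987 ± 468 CPM. The set was called lower (camera adjusted p = 0.0256), which was lost with an estimated correlation (adjusted p = 0.815 with an estimated correlation). Sensory transcription factors likewise had 0 of 18 members called, with 1 higher and 4 lower when adjusted over the list alone. Isl1 stood at 364 ± 100 against 630 ± 233 CPM and Ebf1 at 241 ± 59.0 against 405 ± 91.7 CPM. This set was also called lower (adjusted p = 0.0235), and lost the call (adjusted p = 0.670 with an estimated correlation). No neurogenesis gene of 16 was called, 2 were higher when adjusted over the list alone, and the set was not called (adjusted p = 0.997). Notch1 was at 131 ± 55.9 and 98.5 ± 6.13 CPM and Srrm4 at 100.3 ± 41.0 and 128 ± 48.5 CPM. Of 15 neuropeptide genes, Gal fell and 14 did not pass, with 2 higher and 2 lower when adjusted over the list alone and no set call (adjusted p = 0.835). Penk was at 127 ± 87.9 CPM in the knockout and 70.2 ± 48.2 CPM in the wild type.

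Hoxd3 was the 1 called gene of 4 tested Hox genes, falling from 6.63 ± 3.09 to 0.643 ± 0.261 CPM (log2 fold change -3.26, SE 0.40, adjusted p = 0.00447), also when adjusted over the list alone. Hoxa2 was at 4.05 ± 7.12 and 1.53 ± 1.93 CPM. The Hox set was not called (adjusted p = 0.418). Among 20 apoptosis and p53 target genes none passed. Adjusted over the list alone, 1 was lower. Ccng1 was at 68.3 ± 17.0 and 102 ± 20.1 CPM, and the set was not called (adjusted p = 0.456). Proliferation genes were not called, singly or adjusted over the list alone (0 of 20; set adjusted p = 0.236), with Mki67 at 155 ± 24.8 and 161 ± 65.8 CPM and Top2a at 180 ± 25.1 and 186 ± 75.3 CPM. In the lists for neurogenesis, neuropeptides and Hox genes, the median log2 fold changes of 0.18, 0.51 and 0.96 had the opposite sign to the set tests.

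Glial genes did not differ past the threshold. None of 19 tested members was called, over all genes or adjusted over the list alone, and the set was not called (adjusted p = 0.237). Sox10, the glial and neural crest transcription factor, was at 1274 ± 1402 CPM in the knockout and 918 ± 342 CPM in the wild type, with 3764 CPM in knockout 29 and 390 to 844 CPM in the other knockout libraries. Fabp7 was at 441 ± 146 and 644 ± 156 CPM. Of 5 melanocyte genes none was called, and 1, Tyrp1, was lower when adjusted over the list alone. Kit stood at 79.8 ± 25.8 and 94.7 ± 29.4 CPM and Mitf at 6.30 ± 2.48 and 4.10 ± 1.15 CPM, and the set was not called (adjusted p = 0.948; median log2 fold change 0.54, mean -0.25, test direction down).

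None of 12 endothelial and pericyte genes was called over all genes, whereas 10 were higher when adjusted over the list alone, and the median log2 fold change was 1.11. Kdr was at 159 ± 66.4 against 68.4 ± 27.9 CPM and Cdh5 at 193 ± 76.6 against 85.5 ± 38.9 CPM. The set was called higher by camera with its preset correlation (adjusted p = 3.18e-11) but not otherwise (adjusted p = 0.481 with an estimated correlation, and 0.210 with fry). Macrophage, erythroid, central nervous system and immediate early sets were called higher in the same way (adjusted p = 3.73e-06, 0.00490, 0.00315 and 0.00259). None of these 4 calls held (adjusted p = 0.670 with an estimated correlation for each). Macrophage scores were 2.17 and 2.23 in wild-type 32 and 35, and 3.39 to 4.39 in the other wild-type libraries against 3.69 to 4.40 in the knockout. The same 2 libraries had the lowest endothelial scores (4.48 and 4.79) and erythroid scores (4.51 and 4.33) of all, and stood apart on the first principal component (90.9 and 78.3, others at most 0.176). No gene of these 4 lists was called over all genes, of 14, 10, 13 and 10 tested. Jun was the 1 gene among them that was higher when adjusted over the list alone, at 129 ± 70.0 against 59.2 ± 15.4 CPM. Csf1r was at 64.6 ± 18.5 and 34.7 ± 20.3 CPM, Mrc1 at 65.5 ± 39.4 and 33.9 ± 22.4 CPM, Hbb-y at 1058 ± 421 and 809 ± 410 CPM, Hba-x at 309 ± 377 and 109 ± 50.2 CPM, and Btg2 at 29.9 ± 6.25 and 24.7 ± 9.28 CPM.

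The remaining tissue markers had no called gene, over all genes or adjusted over the list alone, and no set call. Camera gave adjusted p = 0.0726 for mesenchyme, 0.965 for cartilage and bone, 0.349 for muscle and 0.0527 for epithelium. Col3a1 was at 2096 ± 1109 and 1031 ± 607 CPM, Col1a1 at 1644 ± 984 and 1003 ± 795 CPM, Col2a1 at 505 ± 222 and 455 ± 253 CPM and Col11a1 at 192 ± 127 and 166 ± 110 CPM. Myh3 was at 16.6 ± 17.1 and 32.3 ± 35.1 CPM, Actc1 at 12.8 ± 7.68 and 25.4 ± 29.3 CPM, and Cdh1 at 39.1 ± 28.2 and 16.3 ± 8.62 CPM. Epcam was at 144 CPM in knockout 49 and between 1.57 and 4.09 CPM in the other knockout libraries. The 7 tested mitochondrial transcripts did not differ past the threshold, also when adjusted over the list alone (camera set adjusted p = 0.643). Among them, mt-Co1 was at 5001 ± 1048 and 4780 ± 780 CPM and mt-Cytb at 4755 ± 829 and 4518 ± 412 CPM. Of the 13 members of the list, mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 had 0 counts in every library, and mt-Nd3 had at most 9. These were not tested, and how their reads were counted is not given in the sources used here.

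**Figure D2:**
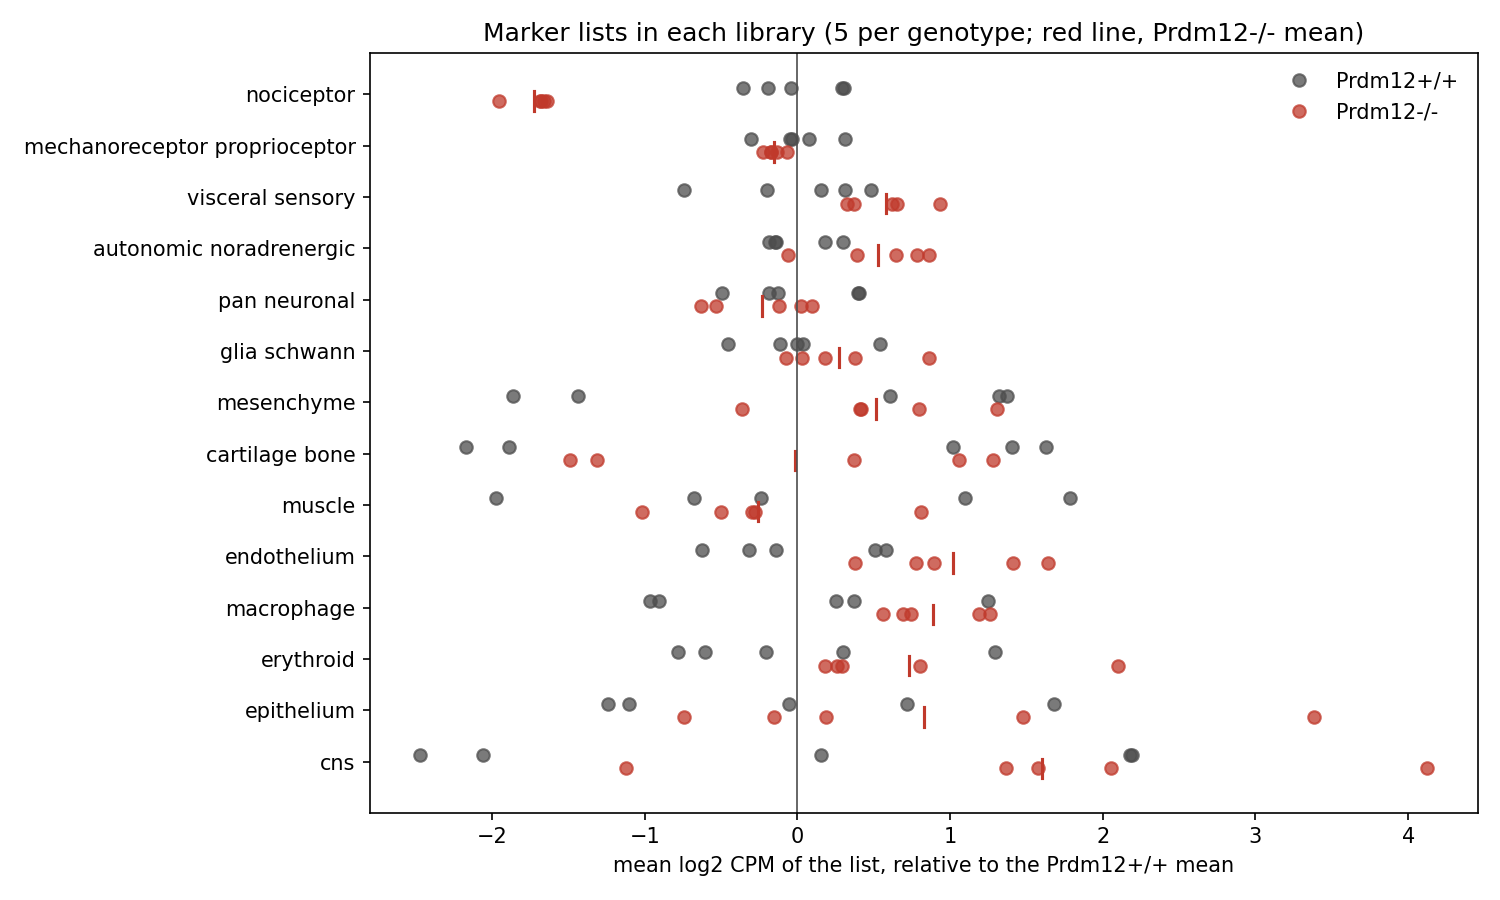
Mean log2 CPM of 14 marker lists in each library, relative to the Prdm12+/+ mean of that list (horizontal axis, log2 units); grey points are 5 Prdm12+/+ libraries, red points 5 Prdm12-/- libraries and red lines the Prdm12-/- mean. The nociceptor list lies 1.72 log2 units below the wild-type mean, with scores of 3.60 to 3.92 in the knockout and 5.20 to 5.86 in the wild type, whereas mesenchyme, cartilage and muscle scores spread widely within both genotypes.

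Both sexes were present in both groups. Xist was at 1602 to 2649 CPM in knockout 16, 49 and 50 and in wild-type 22 and 45, with Ddx3y at 0.0349 to 0.869 CPM there, and the other 5 libraries had 2.53 to 18.4 CPM of Xist and 31.9 to 80.0 CPM of Ddx3y. None of the 5 sex-linked genes was called between genotypes, over all genes or adjusted over the list alone (set adjusted p = 0.653). Eif2s3y was at 29.4 ± 40.3 and 46.6 ± 45.7 CPM, Kdm5d at 20.2 ± 29.4 and 38.2 ± 36.7 CPM and Uty at 11.3 ± 17.8 and 20.7 ± 19.0 CPM in the knockout and the wild type.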

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

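The splits of the libraries into other groups were planned before the data were examined, and the tests of the endothelial genes, of knockout 29 and of outlying values on unlogged CPM were chosen after those results had been seen.

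Of 100 splits of the 10 libraries into 5 and 5, drawn from 126 possible, 1 gave as many called genes as the real split, and that was the real split itself. The real split called 84 genes and the highest other split called 6. A share of 1 in 100 was the smallest that this test could give. The other splits mixed the genotypes, which can raise the spread within groups and lower their number of calls. The test therefore shows only that no other drawn split came near the real one. The split that called 6 put knockout 16, 49 and 50 with wild-type 22 and 45, which are the libraries with high Xist. Of the splits, 97 called 0 genes.

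In 7 of 198 values examined, the gap between 1 library and the nearest of the other 4 of its group was over 0.71 of the group's range (Dixon's ratio, for genes on the scale of log2(CPM + 1)), where chance flags about 1 in 20 groups and so 9.9 were due by chance. Epcam was at 144 CPM in knockout 49 (next highest 4.09) and at 19.4 CPM in wild-type 45 (next highest 2.24). Pitx1 and Lhx3, named outside the rule, were also highest in these libraries (CPM without TMM factors). Pitx1 was at 123 CPM in knockout 49 and 9.2 CPM in wild-type 45, with at most 0.809 CPM (knockout 29) elsewhere. Lhx3 was at 75.2 CPM in knockout 49, and outside these libraries at most 1.1 CPM (knockout 16). Jun was at 253 CPM in knockout 29 (next highest 110.0), and the mean log2 CPM of the immediate early genes there was 4.82 (next highest 3.91). The nociceptor score was lowest in knockout 16 at 3.60 (next lowest 3.87). Fmo2 was lowest in wild-type 45 at 2.68 CPM (next lowest 4.64), and Ntrk2 was lowest in wild-type 32 at 126 CPM (next lowest 167). The scale matters: on unlogged CPM, 15 of 142 gene values passed, 4 of which also passed on the log scale. Those that passed on unlogged CPM alone included Prdm12 (42.7 CPM), Scn10a (26.1), Nefm (4901), Sox10 (3764) and Hba-x (980.2) in knockout 29, and Pax2 (53.6), Lhx1 (35.7) and Hoxa2 (16.7) in knockout 16. Robo3, also named outside the rule, was at 594 CPM without TMM factors in knockout 16 (next highest 52.6, in knockout 50). Whether neighbouring tissue in the dissection was the source of the high Epcam, Pitx1, Lhx3, Pax2, Lhx1 and Robo3 values was not tested.

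The endothelial score was 1.02 higher in the knockout (exact permutation p = 0.0238, or 0.111 adjusted over 14 lists), and the set's camera call was lost (adjusted p = 0.481 with an estimated correlation, and 0.210 with fry). The adjustment over 14 lists could hardly pass any list. Even the nociceptor list, at the smallest possible permutation p of 0.00794, stood at 0.111 after it. A smaller share of neurons among the collected cells could raise every non-neuronal list alike. The endothelial score minus the mean of the mesenchyme, cartilage and muscle scores differed by 0.94 between genotypes (exact permutation p = 0.183). This contrast cannot decide, because the scores of these tissues vary widely within each genotype with 5 libraries each. Glia were not part of it, and the glial score differed by 0.27 (exact permutation p = 0.262). The general neuronal score differed by -0.23 (exact permutation p = 0.349). Macrophage and erythroid scores differed by 0.89 (exact permutation p = 0.0873) and 0.73 (exact permutation p = 0.238). The glial difference was smaller than the endothelial one, but they were not tested against each other. The explanations therefore cannot be told apart. An effect of genotype on the vessels also stays open and was not tested.

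Knockout 29 stood apart from the other libraries, with a second principal component of -92.8 and 3764 CPM of Sox10. Knockout 49, with fewer counts still, had 647 CPM of Sox10, but a part played by depth stays open. A younger embryo cannot be told apart from other causes, because the globin ratios differ: embryonic over adult globin counts were 3.54, within the 1.79 to 6.11 of the others, while Hba-x over Hba-a1 was 3.69, above the highest other value of 2.01. A larger share of glia in the dissection was not tested.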

How the results depend on the processing

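The fits without knockout 29 and 49 together, the fits with the mesenchyme score, the central nervous system score or Xist as a covariate, and the permutation test of Phox2a were chosen after the data were seen.

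All 84 called genes kept their direction in every alternative that tested them, and 7 were not tested under the stricter filter. The 84 were chosen from these same libraries, and 83 of them were separated between the genotypes in every library. A reversal was therefore unlikely from the start, and the kept direction adds little support. Of 2372 values recomputed, 2037 kept their direction and their side of the threshold, 196 lost the threshold, 33 gained it and 106 reversed, of which 105 were past the threshold in neither fit. Among the named genes, Scn10a, Runx1, Gal, Ntrk2, Olfr558, Olfr559, Olfr78, Cdkl4, Ccdc68, Fmo2 and Hoxd3 were called in all 23 alternatives, Trpv1 in 22, P2rx2 in 21, Prdm12 in 20, Alk in 18 and Th in 17. Tmc3, Gata3 and Bhlhe23 were called in 14, Mafa in 13, C1ql3 in 12, Ret, Bdnf and Adora2a in 11, Slc7a11 in 10, and Slc6a11, Cpne7 and Abcc3 in 9. Phox2a was called in 1 (adjusted p 0.0158 to 0.492), with log2 fold changes from 1.81 to 3.68. The nociceptor list stayed past the threshold in all 24 settings (adjusted p 1.1e-39 to 0.0189). The list tests were not run with DESeq2, which gives no input for camera. No scaling moved the median log2 fold change of all genes by more than 0.1. The cause of the changes below was not tested, except where fewer libraries, another threshold or another set of tested genes is itself the change.

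The numbers of higher and lower genes were 55 and 102 without a filter (39450 genes tested), 388 and 236 with DESeq2, 96 and 121 with the mesenchyme score, 4 and 26 with the central nervous system score, 5 and 39 with Xist, and 1 and 26 at an adjusted p of 0.01. Higher genes numbered 26 with the stricter filter, 5 with 1 surrogate variable and 6 without knockout 29 and 49. With single libraries left out, higher genes ranged from 2 to 35 and lower genes from 27 to 88, and between 29 and 68 of the 84 were called again. Higher and lower genes were 35 and 61 without knockout 16, 5 and 31 without knockout 42, 4 and 30 without knockout 49, 3 and 32 without knockout 50, 3 and 49 without wild-type 22, 35 and 78 without wild-type 24, 3 and 29 without wild-type 32, 2 and 27 without wild-type 35, and 6 and 54 without wild-type 45. Without knockout 29 they were 23 and 88.

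Prdm12 stayed lower throughout, at -3.89 to -3.14 with single libraries left out, but missed the threshold without knockout 49 (adjusted p = 0.0561), without knockout 50 (adjusted p = 0.0616) and with the central nervous system score (log2 fold change -2.94, adjusted p = 0.0543). The autonomic list lost its call with the stricter filter (adjusted p = 0.258), an estimated correlation (0.670) and fry (0.342), and ranged from 0.000365 to 0.0609 with single libraries left out, the last without wild-type 22. The general neuronal list lost its call with 1 surrogate variable (0.0869), the mesenchyme score (0.184), the central nervous system score (0.118), Xist (0.145), an estimated correlation (0.815) and fry (0.506). With single libraries left out it ranged from 0.000699 to 0.230, losing the call without knockout 42 or 49 or wild-type 32 or 35. The sensory transcription factor list was past the threshold in 14 of 24 settings. It lost its call without knockout 42 (0.126), knockout 49 (0.0578), knockout 50 (0.0662), wild-type 24 (0.0519) or wild-type 35 (0.0790), with the mesenchyme score (0.0638), the central nervous system score (0.0855) or Xist (0.0665), and with an estimated correlation (0.670) and fry (0.436). The central nervous system, erythroid and immediate early lists were past the threshold in 20 of 24 settings each, and all 3 lost their calls with an estimated correlation (0.670 each) and fry (0.437, 0.437 and 0.436). The central nervous system list also lost its call without knockout 16 (0.0872) and with its own score as a covariate (0.751), a loss that this covariate brings by design. The erythroid and immediate early lists also lost theirs without knockout 29 (0.190 and 0.0636) and without knockout 29 and 49 together (0.117 and 0.0627). The macrophage and endothelial lists, past the threshold in 22 of 24, lost it with an estimated correlation (0.670 and 0.481) and fry (0.436 and 0.210). All other settings of the list tests used camera's preset correlation of 0.01. The estimated correlations were far above it, at 0.816 (macrophage), 0.704 (endothelium), 0.795 (erythroid), 0.683 (central nervous system) and 0.541 (immediate early). For these lists, the number of settings passed therefore says little about whether the call holds. The glial list passed the threshold with Xist as a covariate (0.0122). Other lists without a call in the report passed in some of the settings: mesenchyme in 8 of 24 (lowest adjusted p 0.00527), epithelium in 5 (0.00217), muscle in 4 (0.000335), proliferation in 2 (0.00527) and Hox in 1 (0.0195).

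The mechanoreceptor list, never called, changed direction with size factors (adjusted p = 0.946), upper-quartile scaling (0.987), library size (0.877), no filter (0.811), the stricter filter (0.886), limma-voom (0.977), 1 surrogate variable (0.979), the mesenchyme score (0.991) and fry (0.922), and ranged from 0.533 to 0.982 with single libraries left out. Other lists that reversed, with their adjusted p, were Hox and melanocyte without a filter (0.431 each), melanocyte with the stricter filter (0.471) and limma-voom (0.899), cartilage with limma-voom (0.977), neurogenesis with 1 surrogate variable (0.917), and epithelium (0.955), melanocyte (0.968) and mitochondrial (0.836) without knockout 29 and 49. With the mesenchyme score these were neurogenesis and neurotrophic (0.895 each) and proliferation (0.928), and with Xist the sex-linked list (0.0255), the 1 reversal past the threshold. Xist is a member of the sex-linked list, so this covariate acts on the list directly and the reversal says nothing about genotype.

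Log2 fold changes of uncalled genes reversed as follows. Top2a and Mki67 were 0.00761 and 0.00745 with size factors, 0.0135 and 0.0114 with the stricter filter, 0.00778 and 0.00768 with DESeq2, and 0.0328 and 0.0223 with limma-voom, where Calca was -0.0927. Epcam was -0.76 with 1 surrogate variable. Without knockout 29 and 49, Tbx3 was -0.20, Sox10 -0.49, Col2a1 -0.10, Epcam -1.02, mt-Co1 -0.0735 and mt-Cytb -0.0267. With the mesenchyme score, Nefm was 0.0207, Calca -0.0570, Col11a1 -0.12 and Eif2s3y 0.0317. With the central nervous system score, Nefm was 0.0717, Lhx1 -0.27, Hoxa2 -1.02 and Xist -2.67. With Xist as a covariate, Nefm was 0.0627, Tubb3 0.0248, Ddx3y 0.98, Eif2s3y 1.82, Kdm5d 1.26 and Uty 1.07.

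With single libraries left out, genes that reversed ranged as follows: Tbx3 -0.23 to 0.21, Nefm -0.45 to 0.0281, Tubb3 -0.45 to 0.0277, Calca -0.17 to 0.92, Sox10 -0.46 to 0.70, Col2a1 -0.0515 to 0.38, Col11a1 -0.22 to 0.48, Epcam -0.81 to 4.38, Lhx1 -0.16 to 2.44, Hoxa2 -0.98 to 2.49, Top2a -0.18 to 0.18, Mki67 -0.18 to 0.20, mt-Co1 -0.0393 to 0.21, mt-Cytb -0.000527 to 0.16 and Xist -0.25 to 0.91. Epcam reversed without knockout 49, Lhx1 and Hoxa2 without knockout 16, and Sox10 without knockout 29. The lists that reversed ranged in adjusted p from 0.271 to 0.955 (apoptosis), 0.148 to 0.934 (cartilage), 0.472 to 0.990 (melanocyte), 0.281 to 0.905 (mitochondrial), 0.127 to 0.974 (neurogenesis), 0.662 to 0.990 (neuropeptides), 0.563 to 0.990 (other Prdm genes) and 0.000335 to 0.877 (muscle, lowest without wild-type 32).

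The depth of knockout 49, 3258010 counts, sets a floor of 0.869 CPM there, so values under 1 CPM in that library rest on 3 counts or fewer.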

Other observations

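The genes named in the next paragraph, and the tests of neighbouring genes after it, were chosen after their values were seen.

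Among called genes outside the fixed lists, the potassium channel gene Kcnh6 fell from 85.4 to 8.39 mean CPM, and the channel subunit gene Kcne1l from 38.5 to 11.3 CPM. Pirt, which encodes a membrane protein that binds Trpv1, fell from 513 to 176 CPM. Cdhr1, a photoreceptor cadherin gene, fell from 72.1 to 9.83 CPM. The zinc finger gene Insm2 fell from 5.78 to 1.07 CPM. Among higher genes, Atp1b2, a sodium pump subunit gene, rose from 31.0 to 57.4 CPM and Fa2h, a fatty acid hydroxylase gene, from 0.334 to 1.53 CPM.

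Of 64 called lower genes with a known position, 10 lay within 200 kb of another, where 10000 draws of as many tested genes gave a median of 2 and at most 10 (permutation p = 6e-04). Of these 10, 4 were the olfactory receptor genes Olfr558, Olfr559, Olfr78 and Olfr571, whose grouping had prompted the test. With olfactory receptor genes left out, 6 of 60 lay within 200 kb of another, Usp12 and Rasl11a among them, against a median of 2 and at most 11 in 10000 draws (permutation p = 0.032). Shared regulation, reads shared between similar genes and reads of overlapping genes may each contribute and were not told apart. Of the 10 tested genes on each side of Prdm12 0 were called, with the smallest adjusted p at Lamc3 (log2 fold change 2.40, adjusted p = 0.0827).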
